A study of Homo sapiens with 4 samples.

How the data were processed

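ATAC-seq libraries from cells labelled HepG2, whose identity was not checked, were compared between 2 samples labelled DMSO and 2 labelled TM, grouped by the treatment given in the labels. The second TM sample is titled HEPG2-CEM2, whereas the first is titled HEPG2-TM1. It was kept in TM by its treatment label, but its title names something other than TM, so it is open whether 1 of the 2 TM libraries is from another condition. The submitters' processing notes name cutadapt 2.5, Bowtie2 2.11.1, MACS2 2.1.2 and the build hg38, without their roles. The region caller is not given in the sources used here, and its column names are those of a sliding-window negative binomial comparison.

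The authors deposited 1 table of selected regions. Per the file headers it gives 2 scaled counts per group and region, the group means as signal, a log2 fold change, a p-value and an adjusted p-value, and the best window and gene annotation of each region. The authors scaled the read counts between libraries before they deposited them. The signal columns hold the authors' group means of the scaled counts. The log2 fold change of the authors is that of these means with no pseudocount, and is infinite for 1 region with a DMSO mean of 0. The p-value of the best window was at most 1.0e-04 in the deposited table, so the table is a selection of regions that differ, and the regions tested and not selected were not used here. Error rates of any further test on it do not hold genome-wide. Coordinates are printed as the table gives them. They do not match the build named in the notes: of 8930 genes compared with GRCh38.p14, 394 had their 5′ end within 1000 bp of the position in the table, and 365 regions lay past the last gene of their chromosome. The positions were taken to be those of hg19, which is named as the build of all coordinates here. No comparison with hg19 itself was run.

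The values were found to be whole multiples of 1 step per library, within 0.1 step for 100% of values, so reads were recovered. The steps were 0.979, 0.828, 1.1 and 1.1 for DMSO a and b and TM a and b. A region at a scaled count of 20 thus rests on about as many reads, and its value carries a large counting error, whereas strong regions are more precise. The libraries of each group differed by more than sampling noise (chi-square per degree of freedom 1.4 for DMSO and 1.41 for TM). Each was counted as 1 replicate. That spread does not show separate cultures, since separate libraries of 1 culture can also differ by more than sampling noise. Reads without molecular identifiers are not independent molecules, and exact binomial tests cover counting error only.

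The design fixed before the data were examined called for a count test if per-sample counts were present and otherwise for the authors' calls. No column holds the counts of 1 sample and the cells hold scaled values, so the authors' calls were used. Regions with an adjusted p under 0.05 in the authors' deposited table were counted by the sign of the authors' log2 fold change. The planned count test was not run on the recovered reads, although these would have allowed one. Group means ± SD were computed from the scaled counts, and log2 differences of log2(value + 1) with their SE came from limma 3.58.1 in R 4.3.3, with an empirical Bayes trend. The pseudocount pulls the log2 differences of weak regions towards 0, while the mean of logs can differ from the log of the authors' means either way. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Gene names in the table (8987) were brought to current symbols by transcript accession (8745), symbol (152) or synonym (49), and 41 were unmatched.

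Promoter shares, 23 gene lists fixed in advance and chromosomes were tested with Fisher's exact test, and distances to the start site by 100000 permutations. For lists, genes with all regions higher were set against genes with all regions lower, and the background was every gene with regions in 1 direction. Promoters are the 3 promoter classes of the table's annotation, up to 2999 bp from a start site. Named genes followed a rule fixed in advance: 15 ER stress genes, the 10 genes per direction with the largest fold among promoter regions with a mean of at least 20, the 3 genes per list with the smallest adjusted p, and the 5 regions per direction with the smallest adjusted p. Not every gene so chosen is printed with its value. Level-matched tests in 20 strata, limma calls and binomial tests were added after the data were seen. On simulated data for TM against DMSO with 34370 regions, limma called 0.83 of 4-fold changes. Few regions were changed in that simulation and its spread was assumed, whereas the listed regions were selected for differing. The share called therefore need not hold for them. On 9000 simulated genes the level-matched test passed 0.045 of lists that differed in level alone. The chance of being higher was constant within each simulated stratum. That simulation therefore cannot show an effect of level left inside the strata. Motifs were not analysed here, since no genome was used.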

Results

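Accessible chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in cells labelled HepG2, an established line of human hepatocellular carcinoma. The identity of the cells was not checked. There were 2 libraries from cells given the solvent DMSO and 2 from cells labelled TM, in a series concerned with endoplasmic reticulum (ER) stress. The title of 1 of the TM samples does not name TM, and its treatment label placed it there. The labels do not spell out TM and do not say whether the libraries of a group came from separate cultures, so the spread between them, and every p-value that rests on it, may be technical. The deposited table lists 34370 regions selected by the authors as differing between the groups, on chromosomes 1 to 22. Values are read counts scaled between libraries. Within a group the libraries are called a and b by their place in the table, which does not say which sample each is. Reads recovered in the listed regions numbered 2508729 and 3011486 in DMSO and 2469112 and 2479689 in TM. Total library depth is unknown.

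The comparison of TM with DMSO asks which chromatin sites differ between cells with these 2 labels. In the authors' deposited table, 33991 regions had an adjusted p under 0.05, and these are the regions called higher or lower throughout. TM was higher in 26447 of them and lower in 7544, or 77.8% and 22.2%. The regions higher in TM were weak in DMSO, with a median of 14.5 scaled counts against 39.2 in TM. The regions lower in TM were stronger, with medians of 133 in DMSO and 76.7 in TM. The median log2 difference, fitted with limma on log2(value + 1), was 1.35 for higher and -0.79 for lower regions. Of the called regions, 99.9% had both TM libraries outside the range of both DMSO libraries. Chance gives 33.3% before selection, and the listed regions were selected for differing. Of the lower regions, 3201 reached an absolute log2 fold change of at least 1 in the authors' deposited table.

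Among 15 genes of the ER stress response fixed before the data were examined, 10 had listed regions. Levels are given as mean ± SD (n = 2 per group) and log2 differences of TM minus DMSO as estimate ± SE. Features and distances are those of the deposited annotation, and whether a region lies within a gene or past its end was not checked. HSPA5, which encodes the ER chaperone BiP, had a higher region annotated to its gene body, 6715.5 bp from the start site. The region lay at chromosome 9, 127995501 to 127998400 (hg19, as all positions here). Its level went from 41.8 ± 13.4 to 117 ± 10.9, a 2.82-fold higher value on the log2(value + 1) scale. DDIT3, which encodes the stress transcription factor CHOP, had a higher gene body region that went from 28.3 ± 0.177 to 66.2 ± 25, with a log2 difference of 1.15 ± 0.28. Gene body regions were also higher at TRIB3, a pseudokinase gene induced by stress, by 0.97 ± 0.21, and at both listed regions of HERPUD1, an ER-associated degradation gene, by 1.19 ± 0.29 and 1.21 ± 0.26. EIF2AK3, which encodes the stress sensor PERK, had a higher region annotated to its gene body, 71143.5 bp from the start site (1.61 ± 0.38). Its promoter region was lower, with a log2 difference of -0.34 ± 0.08.

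The listed regions of the remaining genes of this set were lower. A split by position was not particular to this set. Over all called regions, 84.3% of those in gene bodies were higher and 87.9% of those at proximal promoters were lower. At the proximal promoter of CHAC1, a glutathione-degrading enzyme gene, the level went from 349 ± 0.735 to 234 ± 2.39, a log2 difference of -0.58 ± 0.10. PPP1R15A, which encodes the phosphatase subunit GADD34, had lower regions at its proximal promoter (-0.73 ± 0.18) and downstream of it (-0.87 ± 0.13). The promoter of DNAJB9, an ER co-chaperone gene, had a log2 difference of -0.29 ± 0.07. A region 1832 bp from the transcription start site of ATF4, the transcription factor of the integrated stress response, went from 33.2 ± 7.1 to 11 ± 4.68, with a log2 difference of -1.55 ± 0.36. A region of the transcription factor gene ATF3 was lower by a small amount, with a log2 difference of -0.30 ± 0.06. It was annotated to the gene body, 42675.5 bp from the start site of 1 transcript, and other start sites were not checked. Its DMSO level of 864 was nearer the median of called proximal promoters (354) than that of gene body regions (16.8). The table lists no region for XBP1, ATF6, ERN1, ASNS or SDF2L1. A gene without a listed region was not shown to be unchanged.

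**Figure D1:**
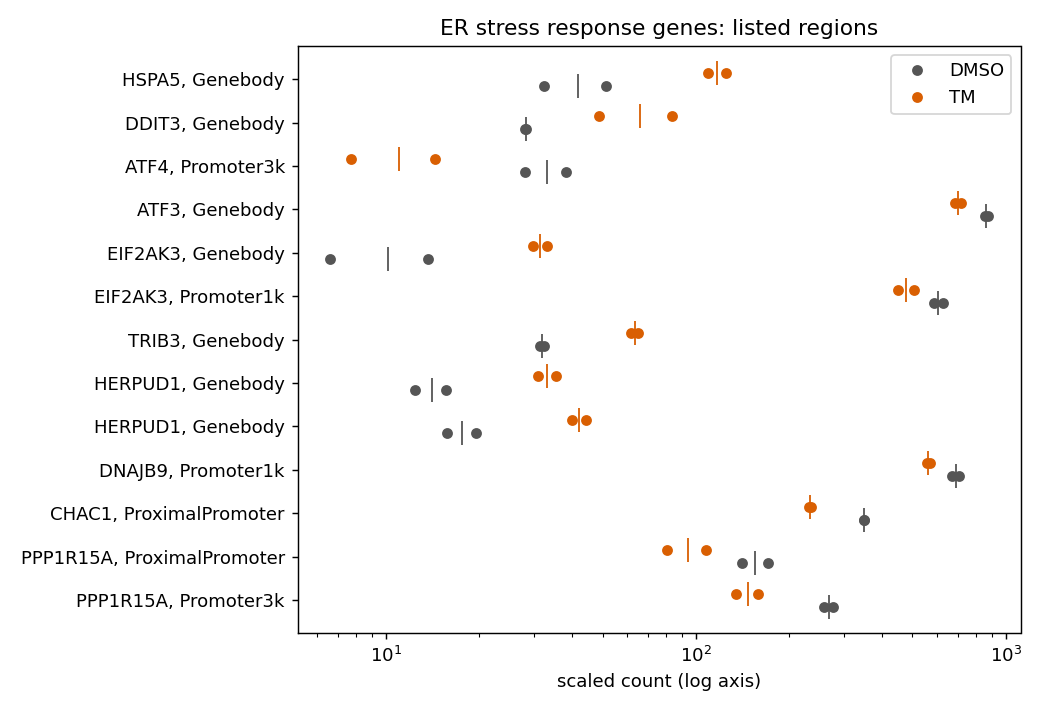
Scaled counts on a log axis at each listed region of the ER stress genes, with 1 point per library, grey for DMSO and orange for TM, and a vertical bar at each group mean. Gene body regions of HSPA5, DDIT3, TRIB3, HERPUD1 and EIF2AK3 lie higher in TM. The promoter regions, and the ATF3 region annotated to the gene body, lie lower. Over all called regions, 84.3% of those in gene bodies were higher and 87.9% of those at proximal promoters lower.

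Direction followed the position of a region relative to genes. Of promoter regions 38.3% were higher in TM, against 85.3% of regions elsewhere, an odds ratio of 0.107 (Fisher's exact test, two-sided, with p below the smallest number the computation could hold). Among regions with an absolute log2 fold change of at least 1 the odds ratio was 0.591. Regions are not replicates, so such tests describe the listed regions and not the spread between cultures. Proximal promoters were lower in 1392 of 1584 cases, and gene body regions were higher in 11646 of 13814. Regions assigned to a gene lay a median of 32306 bp from the start site when higher and 819.5 bp when lower (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give). This difference of 31486 bp was 10091 bp among regions with an absolute log2 fold change of at least 1.

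Direction also followed level. Below a mean level of 50 scaled counts, 88.6% of called regions were higher, and at 200 or more 94.1% were lower. At 200 or more, 97.8% of promoter regions and 82.8% of other regions were lower, with median log2 differences of -0.38 and -0.36. Matched on level in 20 strata, 2077 promoter regions were higher where 2541 were expected (exact conditional test, p = 1.0e-129). The observed number was 0.817 of the expected one. These 2541 were expected among 5424 promoter regions, whereas 77.8% of all called regions were higher. Part of the split by position thus went with level.

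**Figure D2:**
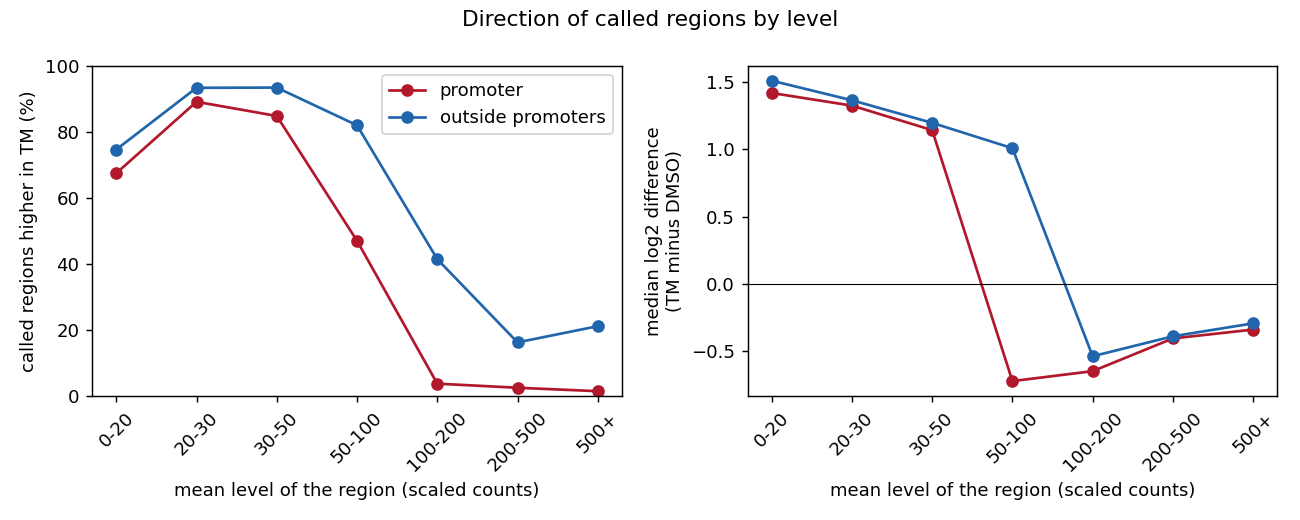
Called regions by mean level in scaled counts, for promoters (red) and other regions (blue). The left panel gives the percentage higher in TM and the right panel the median log2 difference, TM minus DMSO. Regions of low level were mostly higher and regions of high level mostly lower, in promoters and outside them.

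Among gene groups, 18 genes of the AP-1 and immediate early list had all their regions lower and 3 had all higher (adjusted p = 6.6e-04, Fisher's exact test against the other genes, Benjamini-Hochberg over 23 lists). They included DUSP6, a phosphatase gene of the MAP kinase pathway (-0.38 ± 0.08 at its promoter), and the transcription factor gene SRF (-0.58 ± 0.08 in its gene body). In the list of NRF2 oxidative stress genes, 15 were lower and 1 was higher (adjusted p = 4.8e-04). The glutathione reductase gene GSR had a promoter difference of -0.40 ± 0.09, and a gene body region of the cystine transporter gene SLC7A11 went from 29.9 ± 2.16 to 4.97 ± 0.778 (-2.38 ± 0.41). In contrast the gene body region of the transketolase gene TKT was higher, by 1.58 ± 0.25. In the glucose metabolism list 10 genes were lower and 2 were higher (adjusted p = 0.0438), among them PFKFB3 (-0.51 ± 0.11), GAPDH (-0.38 ± 0.09) and LDHA (-0.40 ± 0.09), genes of glycolysis. Each of these 3 lists had 3 further genes with regions both ways. Counted by region, the AP-1 list had 7 higher and 31 lower, the NRF2 list 7 and 21, and the glucose list 13 and 17. Over all genes with regions in 1 direction, 58% were higher. None of these 3 lists passed once the same genes were matched on the mean level of their regions, with adjusted p = 1, 0.827 and 0.827. Nor did they with 2 choices changed, matching on level and each gene taken by its region of smallest adjusted p. Genes going both ways were included there, with adjusted p = 1, 0.418 and 0.412. Among regions with an absolute log2 fold change of at least 1 the adjusted p was 0.0743, 0.0743 and 0.101. The differences there, in percentage points of genes higher against the other genes, were -51.1, -51.1 and -41.6. Over all called regions they were -43.9, -51.9 and -41.4, so these lost calls do not show that the differences went away. With promoter regions only, the AP-1 list (adjusted p = 0.0979, -25.6 points) and the glucose list (adjusted p = 0.188, -26.1 points) did not pass. The glucose list also lost its call at an adjusted p under 0.001 per region (adjusted p = 0.0728), where its difference was no smaller, at -41.9 points. With each gene taken by its region of smallest adjusted p the glucose list did not pass either (adjusted p = 0.0782, -31.3 points). Adjusted over the list alone, 40, 29 and 31 listed regions of the 3 lists passed, against 38, 28 and 30 with the adjustment in the authors' deposited table.

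The lists of regulators and chaperones of the ER stress response did not pass the test. Of the regulators and sensors of the unfolded protein response, genes were 3 higher, 7 lower and 3 both ways (adjusted p = 0.222). ER chaperone and folding genes were 5 higher, 10 lower and 2 both ways (adjusted p = 0.153). In this list a gene body region of PDIA4, a disulfide isomerase gene, went from 15.2 ± 0.742 to 55.2 ± 0.0141 (1.80 ± 0.25), whereas the promoters of P4HB (-0.32 ± 0.10) and DNAJC10 (-0.30 ± 0.08), which encode ER redox proteins, were lower. The promoters of SYVN1 (-0.52 ± 0.10) and OS9 (-0.44 ± 0.10), of ER-associated degradation, were lower. The cell death gene PMAIP1 had a promoter difference of -0.40 ± 0.09, and the gene body region of BIK was higher by 1.60 ± 0.28. Adjusted over the list alone, 23 of the 23 listed regions of the regulators and 26 of the 26 of the chaperones passed, against 23 and 26 with the adjustment in the authors' deposited table.

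The 2 lists of secreted liver proteins and hepatocyte transcription factors did not pass the test. Secreted liver protein genes were 14 higher, 2 lower and 0 both ways (adjusted p = 0.116), and hepatocyte transcription factor genes were 9 higher, 2 lower and 2 both ways (adjusted p = 0.257). At SERPINA1, which encodes alpha-1 antitrypsin, a promoter region at chromosome 14, 94854001 to 94858900 went from 72 ± 4.72 to 202 ± 11.7 (1.47 ± 0.15). Gene body regions of ITIH3 (1.84 ± 0.30), PROX1 (2.09 ± 0.37) and the nuclear receptor gene NR1I2 (1.25 ± 0.24) were higher, and the promoters of APOM (-0.32 ± 0.08) and CEBPD (-0.56 ± 0.09) were lower. Counting promoter regions only, 8 secreted protein genes were higher and 1 lower (adjusted p = 0.0378), and 6 transcription factor genes were higher and 1 lower (adjusted p = 0.0463). At promoters, markers of other cell types went the same way, with 5 genes higher and 2 lower, but did not pass (adjusted p = 0.188). Over all regions and matched on level, the adjusted p was 0.827 for the secreted proteins and 1 for the transcription factors, or 0.727 and 1 with each gene also taken by its region of smallest adjusted p.

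The other lists did not pass, except that with promoter regions only the lists of ERAD and degradation (adjusted p = 0.0452) and of chromatin regulators (adjusted p = 0.0463) had an excess of lower genes, as had the former with each gene taken by its region of smallest adjusted p (adjusted p = 0.0425). Over all regions and matched on level, the adjusted p of these 2 lists was 1 and 1, and it was 1 and 1 with each gene also taken by its region of smallest adjusted p. For ERAD and degradation, genes were 4 higher, 9 lower and 4 both ways (adjusted p = 0.135). The list of ER translocation, glycosylation and ER to Golgi traffic had 4 higher, 7 lower and 1 both ways (adjusted p = 0.337). Genes of the list ATF4 amino acid response were 4 higher, 10 lower and 5 both ways (adjusted p = 0.135). For ER stress cell death, genes were 5 higher, 7 lower and 2 both ways (adjusted p = 0.373). The list of autophagy and lysosome had 4 higher, 7 lower and 4 both ways (adjusted p = 0.337). Genes of the list acute phase and complement were 7 higher, 5 lower and 0 both ways (adjusted p = 1). For lipid and cholesterol metabolism, genes were 11 higher, 12 lower and 5 both ways (adjusted p = 0.509). The list of xenobiotic metabolism and bile acids had 6 higher, 2 lower and 1 both ways (adjusted p = 0.553). Genes of the list p53 targets were 1 higher, 6 lower and 2 both ways (adjusted p = 0.135). For cell cycle, genes were 7 higher, 7 lower and 5 both ways (adjusted p = 0.651). The list of inflammation and NF-kB had 4 higher, 9 lower and 0 both ways (adjusted p = 0.135). Genes of the list Wnt and HCC genes were 8 higher, 2 lower and 5 both ways (adjusted p = 0.337). For EMT and cytoskeleton, genes were 8 higher, 9 lower and 4 both ways (adjusted p = 0.553). The list of chromatin regulators had 10 higher, 7 lower and 10 both ways (adjusted p = 1). Genes of the list heat shock and cytosolic chaperones were 2 higher, 7 lower and 4 both ways (adjusted p = 0.135). For markers of other cell types, genes were 8 higher, 3 lower and 3 both ways (adjusted p = 0.509). Among their named members, gene body regions of GPAM (2.87 ± 0.56, or 2.03 with a pseudocount of 5), a lipid synthesis gene, and ALDH2, an aldehyde dehydrogenase gene, were higher, the latter going from 7.22 ± 0.856 to 32 ± 4.7. Promoters of the cholesterol synthesis gene SQLE (-0.37 ± 0.07) and the replication gene MCM3 (-0.37 ± 0.06) were lower. PHLDA3 and HSPA4L were called lower in the authors' deposited table, but their recovered reads differed by no more than counting error (exact binomial p = 0.167 and 0.13).

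The largest changes at promoters came from weak regions. Among higher promoter regions with a mean of at least 20 in the higher group, the top of the ranking by the fold in the authors' deposited table held OR6A2, CASQ2, IFT27, PHETA1, MCOLN2, MIR4270, KLHL6, PDRG1, CBLN4 and GATD3. The region at CASQ2, a calcium-binding protein gene, went from 2.86 ± 2.87 to 34.8 ± 8.58 (3.42 ± 0.65), and the log2 difference was 4.27 without DMSO library a and 2.58 without DMSO library b, and 2.37 with a pseudocount of 5. The lower ranking held AMBRA1, GIPC3, GGTLC2, EHF, FNBP4, AKR1D1, ADGRE3, MTO1, ASS1 and DLL1. A region near the start site of AMBRA1, an autophagy gene, went from 23.9 ± 2.19 to 3.31 ± 1.56 (-2.57 ± 0.57), and one near ASS1, a urea cycle gene, went from 22.4 ± 1.16 to 4.42 ± 4.69 (-2.45 ± 0.72). The difference at ASS1 was -3.47 without TM library a and -1.42 without TM library b, and with a pseudocount of 5 it was -1.63, and that at AMBRA1 -1.81. Single libraries also moved the values of OR6A2, IFT27, PHETA1, GIPC3, GGTLC2, FNBP4 and DLL1 by over 1.5 times, so the size of these changes is uncertain. Of the regions with the smallest adjusted p in the authors' deposited table, the higher ones included a gene body region of the immune checkpoint gene CD274 at chromosome 9, 5466501 to 5467600, which went from 1.32 ± 0.481 to 29.8 ± 1.56, and 4 intergenic regions. The lower ones included regions at CACTIN (-0.83 ± 0.15), GLIS1 (-0.82 ± 0.13), PRKCH (-0.52 ± 0.12) and ABCC1 (-0.81 ± 0.15) and 1 intergenic region.

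Called regions were spread unevenly over chromosomes. The split of higher and lower differed from the rest on 19 of 22 chromosomes (Fisher's exact test, Benjamini-Hochberg adjusted), and on 11 among regions with an absolute log2 fold change of at least 1. Chromosome 5 had 3766 higher and 516 lower regions (adjusted p = 5.3e-72), and 2682 of the higher ones lay in its first 50 Mb, which is 10.1% of all higher regions. Chromosome 21 had the smallest share of higher regions, 53.4%.

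**Figure D3:**
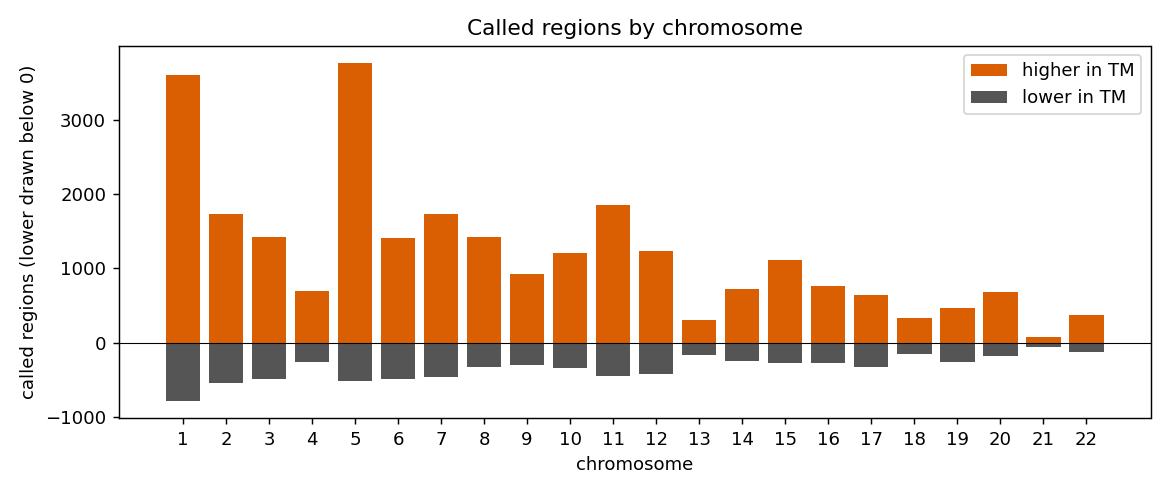
Number of called regions per chromosome, with regions higher in TM drawn above 0 in orange and regions lower in TM drawn below 0 in grey. Chromosome 5 holds 3766 higher regions, the most of any chromosome.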

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

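The limma, binomial and level-matched settings, the omission of the first 50 Mb of chromosome 5, and single-library omissions other than for the counts of regions were chosen after the data were seen. No paired analysis was possible because the table's values carry no replicate labels. The DESeq2 test and all motif settings were not run. Counts of higher regions stayed between 23765 and 26468 under every setting run. Counts of lower regions fell from 7544 to 3201 with an absolute log2 fold change of at least 1, and otherwise stayed between 6665 and 7634. Leaving out 1 library, with no test, kept the direction of 26445 to 26446 higher and 7535 to 7543 lower regions. Selection all but fixed this outcome, since 99.9% of called regions had both TM libraries outside the range of both DMSO libraries. The promoter odds ratio and the distance difference kept their direction and their side of the threshold in every setting run, and with that fold filter the odds ratio was 0.591 and the distance difference 10091 bp. The number of lists past the threshold, 3, became 0 with the fold filter, 5 with promoter regions only and 0 when matched on level, as it did (0) with each gene also taken by its region of smallest adjusted p. With the fold filter the AP-1, NRF2 and glucose lists kept differences of -51.1, -51.1 and -41.6 percentage points of genes higher. These were -43.9, -51.9 and -41.4 over all called regions, so the lost calls do not show that the differences went away. The number of chromosomes fell from 19 to 11 with the fold filter. The cause was not tested for lower regions, lists and chromosomes.

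List differences, in percentage points of genes higher, changed sign as follows. They were taken against the other genes, and when matched on level against the number expected at the same level. A change of sign when matched on level is thus partly a change of measure. With the fold filter they were UPR regulators and sensors 1.3, ER chaperones and folding 3.09, autophagy and lysosome 1.3, acute phase and complement -6.65, markers of other cell types -2.6. Matched on level they were ER chaperones and folding 2.58, ERAD and degradation 1.95, ER stress cell death 3.85, acute phase and complement -2.05, lipid and cholesterol metabolism 2.53, cell cycle 1.49, chromatin regulators -2.17, markers of other cell types -3.74, and with each gene also taken by its region of smallest adjusted p ER chaperones and folding 1.64, acute phase and complement -5.75, lipid and cholesterol metabolism 2.17, cell cycle 1.28, markers of other cell types -0.364. With promoter regions only the value was chromatin regulators -36.1, and with an adjusted p under 0.001 it was chromatin regulators -1.19. The cause was not tested. Of 274 list values, 13 lost and 4 gained significance in the same direction. The 109 named regions gave 654 values with 1 library left out, log2 differences recentred on total counts or a pseudocount of 5. None changed sign, which is no sign of robustness. Where both TM libraries lie outside the range of both DMSO libraries, neither an omission nor a pseudocount can change the sign. This held for 99.9% of called regions, and the recentring shifted values by only 0.143. Leaving out a library moved the values of 11 of the named regions, and the pseudocount those of 22, by over 1.5 times. The regions so moved were weak in 1 group. Weak regions rest on few reads, and the total depth is unknown.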

Other observations

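All tests here were chosen after the data were seen. Regions at marker genes of other cell types were among those higher in TM. Gene body regions went from 24 ± 3.5 to 69 ± 10.1 at the endothelial gene VWF (1.48 ± 0.24) and from 56.8 ± 11 to 125 ± 1.53 at the mesenchymal gene PDGFRB (1.14 ± 0.19), as mean ± SD (n = 2). The list had 10 genes higher by their region of smallest adjusted p, where 10.1 were expected from level.

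Weak regions were higher and strong regions lower in TM. A single scaling factor per library is argued against, since a share of 0.886 of regions under a level of 50 was higher while strong ones were lower. A change at annotated promoters alone is argued against by a share lower of 0.828 among strong regions outside them. Other start sites were not checked, so some of these regions may be promoters that the annotation does not name. Less signal over background in the TM libraries may account for the pattern. It cannot be told apart from an effect of the treatment, because all TM libraries share it. Strong and weak regions differed by -1.71 (log2) between groups and by at most 0.0537 between libraries of 1 group. The listed regions were selected for differing between groups and not between libraries of 1 group, so these sizes cannot be compared. The 3054 weak regions called lower do not decide between less signal over background and an effect of the treatment. Level is the mean of both groups, so a region that lost signal can fall under 50, and such regions were not separated from background.

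The excess of higher regions on the first 50 Mb of chromosome 5 may reflect more copies in both groups, since listed proximal promoters there had 3.28 times the median DMSO level of those elsewhere (95% bootstrap interval 2.82 to 3.71). Whether the TM cells alone also gained copies stays open. The log2 difference at the 32 listed promoters there lay 0.0646 above that elsewhere (95% bootstrap interval 0.0374 to 0.122), but the table holds only regions selected for differing, and a gain could bring promoters that are otherwise lower near 0 and so out of it. Across 101 bins of 20 Mb, which are not independent and include those of the excess, no relation between the number of higher regions and the promoter level was detected (Spearman's rho = 0.074, permutation p = 0.463), nor across the 98 bins left without those of the excess (rho = 0.00425, permutation p = 0.971). Why the excess is this large stays open.

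In 198 called regions the groups differed by no more than counting error in the exact binomial test. A candidate explanation is p-values that fail at high counts. A share of 1 of these regions had a mean level of 200 or more, against 9.06% of all called regions. This share cannot decide, because a selected region with few reads differs by a large fold and so exceeds counting error. Among named regions outside these 198, the authors' p-value could lie far below or far above the binomial one. At GOLGB1 the authors' p-value was 6.4e-11 and the exact binomial p was 0.0156. At OR6A2 they were 3.0e-09 and 1.2e-13. Both genes were chosen after their values were seen. How many other called regions have p-values that fail was not tested. The choices by smallest adjusted p rest on the authors' p-values. At TMEM168 the scaled counts were 539 and 545 in DMSO and 521 and 518 in TM (exact binomial p = 0.335), an example chosen after its values were seen.

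Very high levels were also seen on chromosome 11 in both groups. Group means were 12208 in DMSO and 9744 in TM at the proximal promoter of PGAP2, and 7077 and 5916 at the promoter of YAP1. They were not confined to promoters: an intergenic region at 3443301 to 3445200 had 9656 in DMSO and 8110 in TM. These regions were chosen after their values were seen.

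With each gene taken by its region of smallest adjusted p, genes going both ways included, and matched on level, 14 secreted liver protein genes were higher where 12.1 were expected (exact test, p = 0.221), and 7 ER chaperone genes where 6.72 were expected (p = 1). Neither hypothesis of a difference beyond level was borne out, and these lists are too short to exclude one.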
